A study of Mus musculus with 16 samples.

How the data were processed

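CUT&Tag libraries for Bcl11a and Spi1 were made from sorted MPP3 cells of mouse bone marrow with a commercial kit, per the labels' protocols. Samples were grouped by the target in their title and by the genotype label, which joins WT-iMOS or KO-iMOS with T1 or T2. Replicate numbers were taken from the titles, which also carry 3m. This gave 16 libraries in 6 groups, and none was left out.

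The authors deposited a narrowPeak list for each library, so peaks were called library by library. Bowtie2, SAMtools and MACS2 and the build mm10 are named without versions or settings in the submitters' processing notes; whether a control sample was used in peak calling is not given in the sources used here. Each deposited line gives the peak's position and summit, an integer score, a fold enrichment (a ratio over the caller's local background), and the −log10 of a p-value and of a q-value. Every deposited −log10 q was above 2. Score, fold enrichment and −log10 p are the authors' own values and were used only to rank or filter peaks within a list. The lists carry no read counts, so depth is unknown, no counting interval is given, and a longer list can reflect deeper sequencing as well as more binding. How many peaks a list holds sets the precision of each share. The lists held 2719 to 20241 peaks. No pair of lists had more than 60 identical intervals, so none was treated as a repeat deposit.

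Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Region analyses used the 130097 peaks on assembled chromosomes. Peaks were not filtered against regions known for artefact signal. Peaks of the compared libraries were merged when they shared at least 1 bp, and a merged region was kept when at least 2 libraries had a peak in it. Genes were 21883 protein-coding genes of an annotation table on GRCm38.p6, the assembly that mm10 names. The table gives gene starts and ends but no strand, transcript starts or exons, which led to departures from the planned definitions. A locus was the gene body with 10 kb on either side instead of upstream only. Promoter share was replaced by the share of summits within 1 kb of either gene boundary, with 3 kb as an alternative. Exons, introns and UTRs could not be told apart, so positions are given as inside a gene or at a distance from it. A planned motif search needed genome sequence and was not run.

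Numbers and shares per library were compared by exact permutation of the labels, two-sided as 2 times the smaller tail, and Benjamini-Hochberg values were computed over the 11 measures of each comparison. For T1 against T2 the labels were permuted within each target and genotype. Similarity of lists was the Jaccard index of covered base pairs, tested by exact permutation, one-sided. Overlap of Bcl11a with Spi1 regions was set against 1000 circular shifts of the Bcl11a regions within each chromosome, a background that ignores chromatin accessibility. Presence of a peak per region or gene was compared by Fisher's exact test with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists for 11 lineages and functions were fixed before the data were examined, and 294 of their 295 genes were found in the table. Some genes stand in more than 1 list. In WT-iMOS, the number of list genes with a peak in at least 2 libraries was set against 10000 random lists matched on decile of locus length, two-sided, with Benjamini-Hochberg adjustment over both targets and all lists. For KO-iMOS against WT-iMOS the share of list genes with a peak, less the share of all genes in the same library, was compared by exact permutation.

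The genes, the leading regions of each comparison and the strongest regions were chosen by a rule fixed before the data were examined. The rule did not say which region at a named gene to give. Regions given at named genes were picked after the data were seen, so their library counts are examples only. From each list it took up to 4 genes with Bcl11a in at least 3 of 6 libraries and up to 2 genes with Spi1 in at least 4 of 6 and Bcl11a in 0. For the genotype comparison it took up to 4 genes per list whose share of libraries differed by at least 0.5, and the 10 regions with the smallest p in each direction. For T1 against T2 it took 5 regions in each direction, and for strength the 5 regions with the highest mean percentile of the deposited −log10 p in each target. Not every gene it took is named. Bcl11a and Spi1 were always named.

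The main tests were run on simulated data. For the genotype comparison of regions, presence was drawn for 19529 regions with some changed completely. An unchanged region had the same chance of a peak in every library. The draws thus lack the unequal list lengths of the data, and their number of false calls does not carry over to them. With 200 changed regions all 200 had an unadjusted p under 0.05 and 0 passed the adjustment; with 2000 changed regions 2000 passed, along with 13 unchanged ones. For the Spi1 gene list test on 21883 genes, 2.50% of 200 random lists passed at an unadjusted 0.05, and 20 of 20 lists in which 15 of 30 genes were given peaks passed.

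Alternatives fixed before the data were examined were a −log10 q of at least 3, each library left out in turn, covered length in place of peak number, lists shortened to equal length by −log10 p, regions in at least 3 libraries, summits widened by 100 bp, shared length of at least 50% of the Bcl11a region, other rules linking peaks to genes, T1 or T2 alone, and the replicate number as a block.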

Results

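Binding of the transcription factors Bcl11a and Spi1 was profiled by CUT&Tag in MPP3 cells, a multipotent progenitor population sorted from mouse bone marrow. CUT&Tag tethers a transposase to an antibody, so that DNA near the bound factor is cut and tagged for sequencing. Bcl11a is a zinc finger repressor best known for silencing fetal globin genes, and Spi1 (PU.1) is an ETS factor required for myeloid and lymphoid development. The 16 libraries formed 6 groups. Bcl11a was profiled in WT-iMOS mice, with 3 T1 and 3 T2 libraries. Spi1 was profiled in WT-iMOS mice, with 3 T1 and 3 T2 libraries, and in KO-iMOS mice, with 2 T1 and 2 T2 libraries. The labels do not say what iMOS, T1 and T2 stand for, nor whether replicates came from separate animals. The p-values of comparisons between libraries therefore measure the spread between these samples only. Those from shifted regions or from random gene lists hold the libraries fixed and do not measure that spread. The study's stated purpose was to learn how Bcl11a acts in MPP3 cells. Each library was given as a list of peaks on the mm10 genome, 131939 peaks in all. Read counts were not used here and the depth behind each list is unknown.

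The first question is where Bcl11a and Spi1 bind in WT-iMOS cells. Regions called for Bcl11a were shared with Spi1 far more often than shifted regions. The Spi1 lists held 8159 ± 2763 peaks (mean ± SD, n = 6) and the Bcl11a lists 4740 ± 1725 (n = 6), a ratio of 0.581 for Bcl11a over Spi1 (exact two-sided permutation p = 0.0238, and 0.0655 after Benjamini-Hochberg adjustment over 11 measures compared per library). Peaks found in at least 2 libraries of a target were merged into 6353 Bcl11a regions and 10496 Spi1 regions. Of the Bcl11a regions 4358 (68.6%) shared at least 1 bp with a Spi1 region, against a mean of 0.497% and a maximum of 0.897% when the regions were shifted along their chromosomes (1000 circular shifts, one-sided permutation p = 0.000999, the smallest they can give). With every list shortened to 2719 peaks the share was 38.7%, so its size depends on list length (one-sided permutation p = 0.000999). Conversely 41.6% of the Spi1 regions shared a Bcl11a region. Signal common to both antibodies without binding was not filtered out and could add to these shares. Of the 1995 Bcl11a regions without Spi1, 42.4% were within 1 kb of a gene boundary, compared with 26.3% of those with Spi1, a contrast that was not tested. The shares were 32.8% and 20.6% with lists of equal length, and 23.9% and 16.3% without Bcl11a T1 replicates 2 and 3, whose peaks lay near boundaries more often than those of the other Bcl11a libraries. Despite the sharing, lists of the same target were more alike than lists of different targets. The mean Jaccard index of covered base pairs was 0.267 ± 0.0577 (SD over 15 pairs) among Bcl11a lists, 0.356 ± 0.0476 (SD over 15 pairs) among Spi1 lists and 0.196 ± 0.0371 (SD over 36 pairs) between targets (within minus between 0.116, exact one-sided permutation p = 0.00216, the smallest possible).

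**Figure D1:**
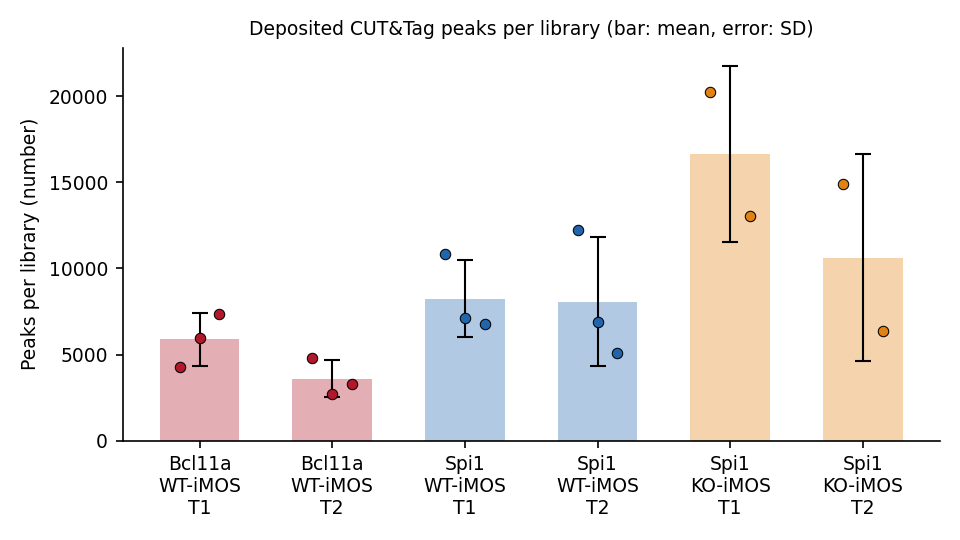
Number of deposited peaks per library (y axis) in the 6 groups (x axis), with points for libraries, bars for means and error bars for SD. Bcl11a lists held 2719 to 7382 peaks, Spi1 WT-iMOS lists 5068 to 12261 and Spi1 KO-iMOS lists 6372 to 20241.

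**Figure D2:**
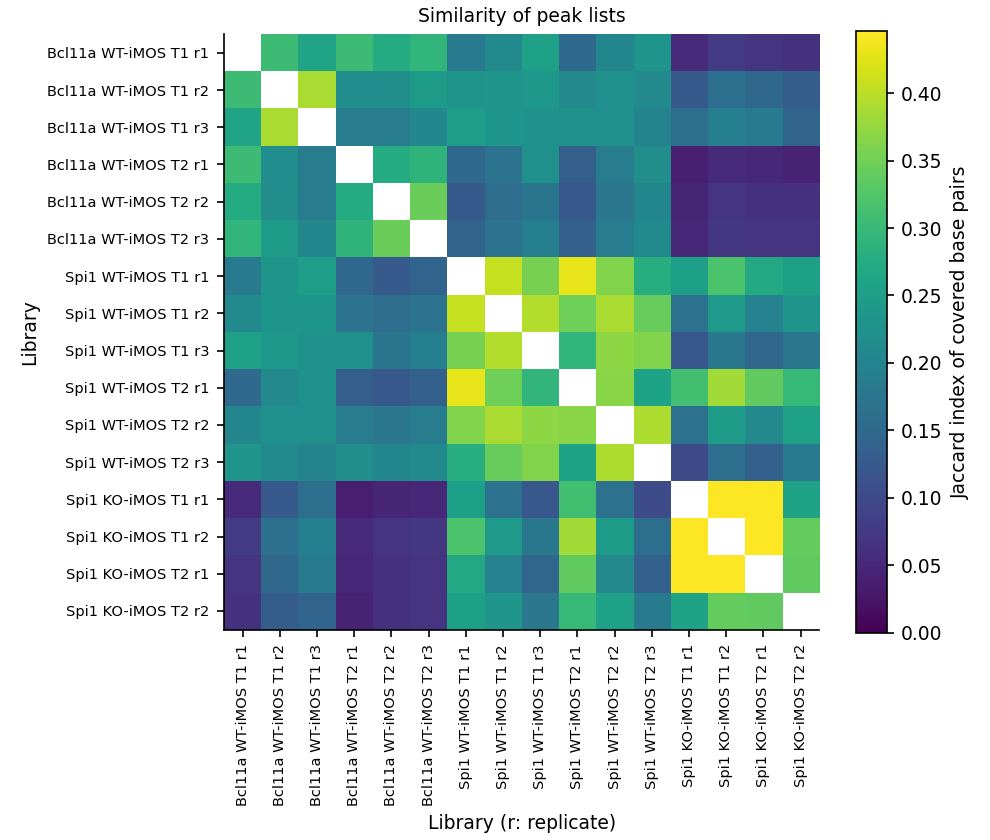
Jaccard index of covered base pairs (colour scale) for each pair of the 16 libraries, on both axes; the diagonal is left blank. The mean was 0.356 within Spi1 WT-iMOS, 0.379 within Spi1 KO-iMOS and 0.0917 between Bcl11a WT-iMOS and Spi1 KO-iMOS.

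Loci of several myeloid receptor and effector genes carried both factors in every WT-iMOS library. Csf1r, the macrophage colony-stimulating factor receptor, had Bcl11a in 6 of 6 and Spi1 in 6 of 6 libraries, with a region inside the gene at chromosome 18, 61107759 to 61109034 (Bcl11a in 6, Spi1 in 5). The same counts of 6 and 6 were found at Csf2ra, a subunit of the GM-CSF receptor, at Fcgr3, an Fc receptor, and at Ncf4, an NADPH oxidase subunit. Their regions lay at chromosome 19, 61226882 to 61228621, chromosome 1, 171063764 to 171066146, and chromosome 15, 78256437 to 78258528, each centred inside the gene. In KO-iMOS, Spi1 was called in 4 of 4 libraries at these regions of Csf1r, Csf2ra and Fcgr3, and in 3 at that of Ncf4. Spi1 without Bcl11a was called at Csf2rb, the shared beta subunit of cytokine receptors (Spi1 in 6, Bcl11a in 0), and at Cybb, the phagocyte oxidase heavy chain (Spi1 in 5, Bcl11a in 0). In the list of 36 granulocyte and monocyte genes, 15 had a Bcl11a peak at the locus in at least 2 libraries against 7.87 in length-matched random lists (permutation test on random lists, adjusted p = 0.0308), and 20 had a Spi1 peak against 10.3 (adjusted p = 0.0169). A locus here is the gene body with 10 kb on either side, and 13 genes of this list carried both factors. The neighbouring genes Elane and Prtn3 both count for each factor, through regions that their loci share. For Bcl11a these were 2 regions, each called in 1 library. The random lists were matched on locus length but not on expression, chromatin accessibility or neighbouring genes. A count above them, here and in the lists below, need not be particular to the programme a list names.

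Genes of cell division and survival were also occupied by both factors more often than matched lists. Of 26 such genes 14 carried Bcl11a (6.48 in random lists) and 16 carried Spi1 (8.65 in random lists), each with an adjusted permutation p of 0.0169. Examples were Ccnd2, a D-type cyclin, with Bcl11a in 5 and Spi1 in 6 libraries over a gene boundary at chromosome 6, 127151231 to 127152891, and Bcl2l1, which encodes the survival factor Bcl-xL, with Bcl11a in 5 and Spi1 in 6. The Ccnd2 region was called for Spi1 in all 4 KO-iMOS libraries. Cdk6, a G1 kinase, had both factors in 6 libraries. Its region at chromosome 5, 3436148 to 3438547 (Bcl11a in 5, Spi1 in 5) was called in 0 of the 4 KO-iMOS libraries. Each of these had a Spi1 peak elsewhere at the locus. Another Cdk6 region, chromosome 5, 3479720 to 3480440 (Bcl11a in 6, Spi1 in 6), was called in 2 KO-iMOS libraries. Rb1 (Spi1 in 5) and Cdc25a (Spi1 in 4) had Bcl11a in 0 libraries. Among interferon and inflammation genes 16 of 25 carried Spi1 (7.60 in random lists, permutation, adjusted p = 0.0169). For Bcl11a the number was 10 of 25 (5.76 in random lists, permutation, adjusted p = 0.144). Ifngr1, a subunit of the interferon gamma receptor, had both factors in 6 libraries at its gene boundary, chromosome 10, 19591410 to 19592296. Spi1 was called at this region in all 4 KO-iMOS libraries. The signalling factor Stat3 had Bcl11a in 6 and Spi1 in 4, whereas the cytokine gene Il1b and Nfkb1 had Spi1 in 6 and Bcl11a in 0. Housekeeping genes carried Bcl11a in 12 of 24 cases (5.21 in random lists, permutation, adjusted p = 0.0169) and Spi1 in 11 (adjusted p = 0.187). For Bcl11a the ratio to random lists was 2.30 here, above the 2.16 of cell cycle and the 1.91 of granulocyte and monocyte genes. Eef2 and Hnrnpa1 had Bcl11a in 6 libraries and Spi1 in 5 and 2. Rps18 had both in 6, with a shared region 8245 bp from the gene, chromosome 17, 33963416 to 33964405, called in 1 KO-iMOS library.

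Lists for other lineages did not pass the test in either direction. Stem and progenitor genes carried Bcl11a in 9 of 30 cases (permutation, adjusted p = 1) and Spi1 in 15 (adjusted p = 0.469). Runx1 had both factors in 6 libraries, Lyl1 had Bcl11a in 4 and Spi1 in 6, and Tal1 had Spi1 in 4 and Bcl11a in 0; all 3 encode transcription factors of blood stem cells. The Runx1 region at chromosome 16, 92757828 to 92758679 (Bcl11a in 5, Spi1 in 4) was called in 0 KO-iMOS libraries, and that at 92800796 to 92802151 (Bcl11a in 3, Spi1 in 6) in 4. Lymphoid genes carried Bcl11a in 10 of 34 (permutation, adjusted p = 1) and Spi1 in 19 (adjusted p = 0.0735), with both factors in all 6 libraries at Bach2 and at Notch1. Shared Notch1 regions at chromosome 2, 26482968 to 26483932 and 26512993 to 26513890 (both factors in 6) were called in 4 of 4 KO-iMOS libraries. Near Flt3, a receptor of early progenitors, and Il2ra, the interleukin 2 receptor alpha chain, shared regions outside the genes were called in 0 KO-iMOS libraries (chromosome 5, 147403817 to 147404361, Bcl11a in 4 and Spi1 in 4, and chromosome 2, 11639201 to 11639840, Bcl11a in 5 and Spi1 in 5). Erythroid genes carried Bcl11a in 7 of 27 (permutation, adjusted p = 0.983) and Spi1 in 10 (adjusted p = 0.623). Ank1, an ankyrin of the red cell membrane skeleton, had both in 6, with a shared region inside the gene at chromosome 8, 23095474 to 23095825 called in 1 KO-iMOS library. At Nfe2, a bZIP factor of the erythroid and megakaryocyte lineages, Bcl11a was called in 6 and Spi1 in 3 libraries; its locus overlaps that of the neighbouring Hnrnpa1, and the 2 share the region at chromosome 15, 103239341 to 103240384. Megakaryocyte genes carried Bcl11a in 10 of 24 (permutation, adjusted p = 0.196) and Spi1 in 14 (adjusted p = 0.0562), among them Itga2b with Bcl11a in 5 and Spi1 in 1. Dendritic genes carried Bcl11a in 8 of 20 (permutation, adjusted p = 0.283) and Spi1 in 11 (adjusted p = 0.121). Mast cell, basophil and eosinophil genes carried Bcl11a in 2 of 18 (permutation, adjusted p = 0.349) and Spi1 in 6 (adjusted p = 1). Genes of non-haematopoietic tissues were occupied less often than matched lists, by Bcl11a in 1 of 30 (6.79 in random lists, permutation, adjusted p = 0.0233) and by Spi1 in 2 (8.92 in random lists, adjusted p = 0.0169). The leptin receptor gene Lepr was the Bcl11a exception, with both factors in 6 libraries at chromosome 4, 101769331 to 101770285. In KO-iMOS the same permutation test, adjusted over its 11 lists, passed for Spi1 at granulocyte and monocyte genes (24 of 36, 16.3 in random lists, adjusted p = 0.0264), cell cycle genes (20 of 26, adjusted p = 0.0225), interferon and inflammation genes (19 of 25, adjusted p = 0.0225), housekeeping genes (18 of 24, adjusted p = 0.0225) and, below random lists, non-haematopoietic genes (1 of 30, adjusted p = 0.0022).

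These list results depended on settings. The permutation test passed 8 combinations of factor and list with all peaks and none when only summits within 1 kb of a gene boundary counted. With lists of equal length it passed 5: Bcl11a at cell cycle, housekeeping and interferon genes (the last at an adjusted permutation p of 0.0238) and Spi1 at granulocyte and interferon genes. Without Bcl11a T1 replicates 2 and 3 together, chosen after the data were seen, no Bcl11a list passed. The Bcl11a call for granulocyte and monocyte genes was lost without T1 replicate 2 (permutation, adjusted p = 0.503), T1 replicate 3 (0.659), T2 replicate 1 (0.0539) or T2 replicate 2 (0.0550). That for cell cycle genes was lost without T1 replicate 2 (permutation, adjusted p = 0.133), and that for non-haematopoietic genes without T1 replicate 2 (0.133) or T1 replicate 3 (0.160). For Spi1, the cell cycle and the non-haematopoietic calls were lost without T1 replicate 1 (permutation, adjusted p = 0.0781 and 0.0515) or T2 replicate 1 (0.0616 and 0.0616). The megakaryocyte list passed for Spi1 without T2 replicate 3 (permutation, adjusted p = 0.0494).

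**Figure D3:**
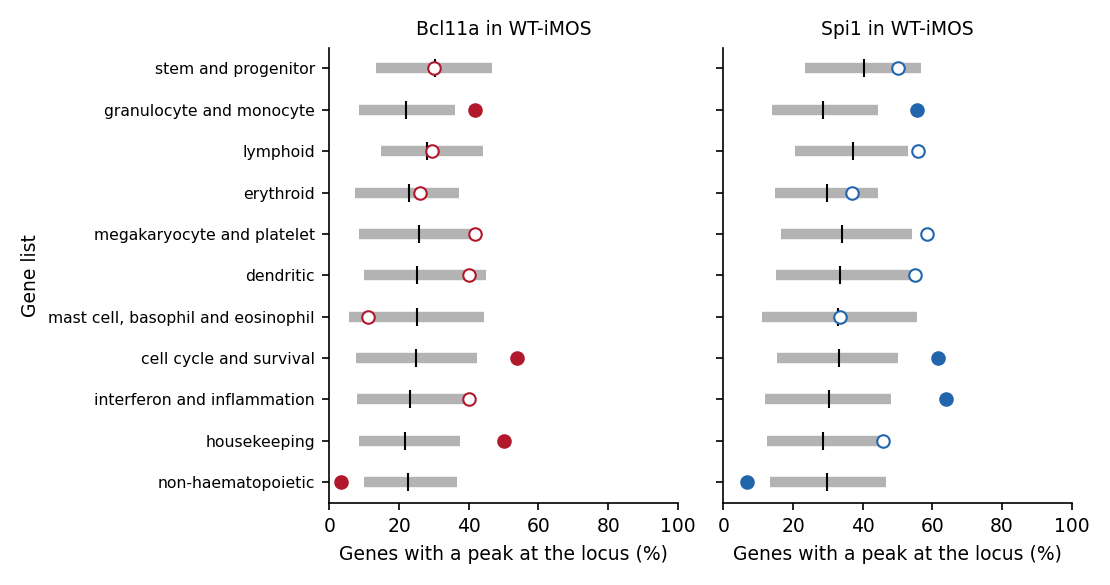
Percentage of genes of each fixed list (y axis) with a peak at the locus in at least 2 of 6 WT-iMOS libraries (x axis), for Bcl11a and Spi1. Grey bars span the central 95% of 10000 length-matched random lists, ticks mark their mean, and filled points mark an adjusted p under 0.05. Granulocyte and monocyte genes stood at 15 of 36 for Bcl11a and 20 of 36 for Spi1.

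The second question is how Spi1 binding differs between KO-iMOS and WT-iMOS cells. A larger share of Spi1 peaks lay near genes in KO-iMOS than in WT-iMOS. The KO-iMOS lists held 13637 ± 5724 peaks (n = 4), 1.67 times the 8159 ± 2763 of WT-iMOS (n = 6), a difference that did not pass the exact two-sided permutation test (p = 0.0762). Within T1 the means were 16647 and 8252 and within T2 10627 and 8066; neither can go below an exact p of 0.2. Without KO-iMOS T2 replicate 2, the shortest KO-iMOS list, the difference passed the exact permutation test (p = 0.0238). Covered length was 7.12 Mb ± 3.12 (n = 4) against 3.56 Mb ± 1.37 (n = 6, exact permutation p = 0.0381, adjusted 0.0466). The share of peaks with a summit within 1 kb of a gene boundary was 32.8% ± 1.40 (n = 4) in KO-iMOS and 21.2% ± 2.78 (n = 6) in WT-iMOS, with all 4 KO-iMOS libraries above all 6 WT-iMOS libraries (exact permutation p = 0.00952, the smallest possible, adjusted 0.0131). Other properties of the lists parted the genotypes in the same way. The narrowest peak measured 250 to 321 bp in KO-iMOS and 202 to 220 bp in WT-iMOS, and the median width was 474 bp ± 22.8 (n = 4) against 372 bp ± 21.9 (n = 6), both at exact permutation p = 0.00952. Peak names in the files began with PWT in the KO-iMOS T1 lists and PKO in the KO-iMOS T2 lists, and with PWG and BWG in the WT-iMOS T1 lists and PMG and BMG in the WT-iMOS T2 lists. Groups here follow the labels, which do not explain these prefixes. If the prefixes name other groups, every value by genotype or T here changes its meaning. If KO stands for a gene deletion that the KO-iMOS T1 cells lack, the KO-iMOS values join 2 kinds of cells.

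**Figure D4:**
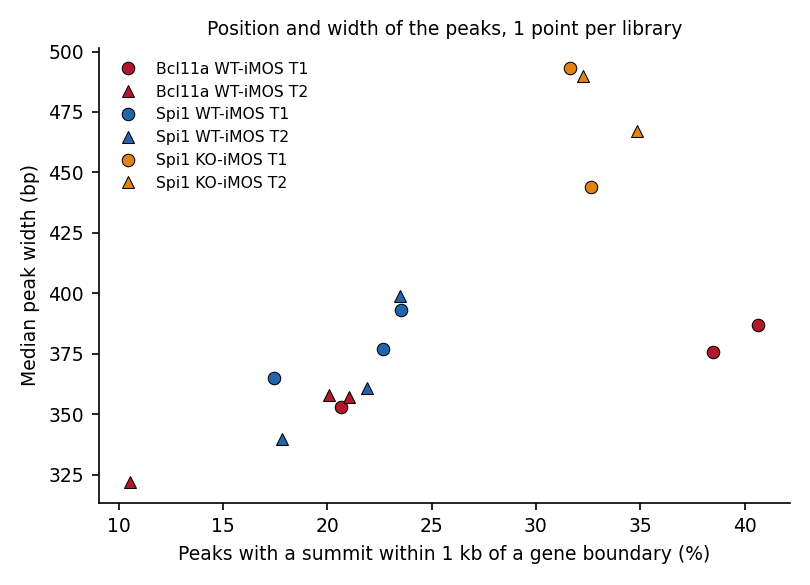
Percentage of peaks within 1 kb of a gene boundary (x axis) and median peak width in bp (y axis), 1 point per library. The 4 Spi1 KO-iMOS libraries have median widths of at least 444 bp, above the 340 to 399 bp of Spi1 WT-iMOS, and Bcl11a T1 replicates 2 and 3 lie at 38.5% and 40.7% on the x axis.

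The KO-iMOS lists reached more genes than the WT-iMOS lists, with a Spi1 peak at 42.6% ± 12.9 (n = 4) of all genes against 25.0% ± 7.56 (n = 6). Single genes are to be read against that rise. Hemgn, a nuclear protein of red cell precursors, and Ccnb1, the mitotic cyclin B1, had a Spi1 peak in 4 of 4 KO-iMOS and 0 of 6 WT-iMOS libraries. So did Epor, the erythropoietin receptor, where Bcl11a was called in 3 of 6 WT-iMOS libraries. Its region at chromosome 9, 21955411 to 21956164 lay 3110 bp from the gene. The stem and progenitor genes Cd34, Myb and Slamf1 and the neutrophil granule gene Ltf had a peak in 4 of 4 against 1 of 6. The Myb region inside the gene, chromosome 10, 21151113 to 21151589, was called in 4 and 0 libraries. Elane and Prtn3, neighbouring genes of neutrophil proteases, stood at 4 of 4 against 2 of 6. Nfkbia, the inhibitor of NF-kappaB, stood at 3 of 4 against 0 of 6 and carried Bcl11a in 4 of 6. A lower KO-iMOS count was found at Lepr (1 of 4 against 6 of 6). A share of libraries higher by at least 0.5 in KO-iMOS was found for 8 of 30 stem and progenitor genes, 7 of 24 megakaryocyte genes, 7 of 26 cell cycle genes, 6 of 27 erythroid genes and 6 of 24 housekeeping genes. It was found for 6 of 36 granulocyte and monocyte, 5 of 34 lymphoid, 4 of 20 dendritic, 2 of 18 mast cell, 3 of 25 interferon and 1 of 30 non-haematopoietic genes, for 18.1% of the genes of all lists and for 22.4% of all genes. Genes lower by as much were found in the cell cycle list (1) and the non-haematopoietic list (2).

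None of these genes passed the adjustment. Fisher's exact test with Benjamini-Hochberg adjustment called 0 of 21883 genes (smallest adjusted p = 0.264), and 0 in every list when adjusted over the list alone. The p of this test cannot go below 0.00476 with these libraries. Many genes genome-wide, or several of a list, would have to reach it before any could pass. At an unadjusted p under 0.05 it gave 1828 genes higher in KO-iMOS and 194 higher in WT-iMOS. Measured against the share of all genes with a peak in the same library, no list differed between genotypes after adjustment (exact permutation, Benjamini-Hochberg over 11 lists). The exact permutation p cannot go below 0.00952 here, and a list that reaches it alone adjusts to 0.105. Several lists would have to reach it before any could pass, so a lack of difference cannot be read from this. Mast cell, basophil and eosinophil genes had an excess over all genes of -16.2 percentage points in KO-iMOS and -3.75 in WT-iMOS (difference -12.5, exact permutation p = 0.00952, adjusted p = 0.105). For non-haematopoietic genes the difference was -15.9 points (exact permutation, adjusted p = 0.157). The shares of these 2 lists were themselves no lower in KO-iMOS (26.4% against 21.3%, and 6.67% against 5%), so with all peaks the deficits come from the rise over all genes. With lists of equal length they were -6.45 (exact permutation p = 0.0476, adjusted 0.0873) and -6.63 points (p = 0.00952, adjusted 0.0524). Stem and progenitor genes differed by 8.55 points and megakaryocyte genes by 8.13 (exact permutation, adjusted p = 0.210 for each), and these turned to -8.08 and -2.46 when only summits within 1 kb of a gene boundary counted, a setting that took granulocyte and monocyte genes to -13.7 (exact permutation p = 0.00952, adjusted 0.0698). By the same exact permutation test the difference was 8.13 points for housekeeping genes (adjusted p = 0.432), 4.97 for erythroid (0.314), 2.63 for cell cycle (0.733) and 0.771 for dendritic genes (0.886). It was -6.56 for interferon and inflammation (0.349), -3.44 for granulocyte and monocyte (0.389) and -3.35 for lymphoid genes (0.687). When each peak counted for the nearest gene boundary within 50 kb, stem and progenitor genes stood at 14.9, cell cycle at 12.3, dendritic at 11.9 and lymphoid genes at -9.79. No list passed the adjustment there. With the replicate number as a block, cell cycle genes turned to -0.697 and dendritic genes to -1.66. Single libraries moved some of these. Without KO-iMOS T2 replicate 2, housekeeping genes stood at 17.5 (exact permutation p = 0.0238, adjusted 0.0873) and lymphoid genes at 1.04, and without KO-iMOS T1 replicate 1 housekeeping genes stood at 2.64. Dendritic genes turned to -4.24 without KO-iMOS T1 replicate 2 and to -0.723 without WT-iMOS T2 replicate 3, and stood at 4.86 without KO-iMOS T2 replicate 2. Lists of equal length changed some of these: housekeeping genes turned to -6.91 (exact permutation p = 0.0286, adjusted 0.0873) and granulocyte and monocyte genes to 1.19, and dendritic genes rose to 8.09, erythroid genes to 7.75 and megakaryocyte genes to 13.9 (exact permutation p = 0.00952, adjusted 0.0524).

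Region by region, 19529 Spi1 regions found in at least 2 of the 10 libraries were tested and 0 passed the adjustment (Fisher's exact test, smallest adjusted p = 0.107). With 4 against 6 libraries the smallest p is 0.00476, and 1860 regions would have to reach it before any could pass. At an unadjusted p under 0.05, 3004 regions were higher in KO-iMOS and 762 in WT-iMOS; with every list shortened to 5068 peaks the numbers were 705 and 586. Without KO-iMOS T1 replicate 1 the higher count was 1231, without T1 replicate 2 1578 and without T2 replicate 1 1321. Regions in all 4 KO-iMOS and no WT-iMOS library numbered 533, and regions in all 6 WT-iMOS and no KO-iMOS library numbered 338. Position separated the regions at an unadjusted p under 0.05: 39.3% of those higher in KO-iMOS were within 1 kb of a gene boundary, 3.15% of those higher in WT-iMOS, and 28.1% of all tested. By the fixed order, the leading regions of the first kind included chromosome 7, 16570891 to 16571595 inside Arhgap35, chromosome 1, 92180267 to 92180923 inside Hdac4 and chromosome 12, 4279245 to 4280001 inside Ncoa1. Leading regions of the second kind included chromosome 13, 120321364 to 120321696, 3269 bp from Tcstv3, chromosome 9, 24542019 to 24542248, 14913 bp from Dpy19l2, and chromosome 16, 93789191 to 93789452 inside Dop1b.

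Among regions called for Bcl11a in WT-iMOS cells, the share with a Spi1 peak differed between genotypes in a way that depended on distance to genes. Over all 6353 Bcl11a regions, 45.2% ± 12.2 (n = 4) held a Spi1 peak in KO-iMOS and 51.8% ± 9.29 (n = 6) in WT-iMOS (exact permutation p = 0.419). With every list shortened to equal length the shares were 19.96% and 30.8%, a difference of -10.8 points that passed (exact permutation p = 0.00952). Bcl11a regions within 1 kb of a gene boundary held a Spi1 peak more often in KO-iMOS, 74.5% ± 19.6 (n = 4) against 42.9% ± 15.04 (n = 6, exact permutation p = 0.0286). Within each genotype this share rose with list length: KO-iMOS T2 replicate 2, with 6372 peaks, stood at 46.0%, below the 59.8% and 62.3% of replicate 1 in WT-iMOS T1 and T2. With equal lengths the difference was 9.51 points (32.0% against 22.4%, exact permutation p = 0.00952). Those farther away held one less often, 31.8% ± 8.78 (n = 4) against 55.8% ± 7.14 (n = 6, exact permutation p = 0.00952). This division by distance was chosen after the data were seen. From the side of Spi1, 22.6% ± 4.25 (n = 4) of KO-iMOS peaks lay in Bcl11a regions, against 43.5% ± 6.92 (n = 6) of WT-iMOS peaks (exact permutation p = 0.00952); the T1 means were 20.5% and 43.4% and the T2 means 24.7% and 43.6%. Without Bcl11a T1 replicate 2 or 3 the overall difference in occupied Bcl11a regions passed the exact permutation test (-15.2 points, p = 0.0286, and -16.6 points, p = 0.0190). The Bcl11a regions come from WT-iMOS libraries alone, and all 4 KO-iMOS lists also differed from the WT-iMOS lists in peak width.

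**Figure D5:**
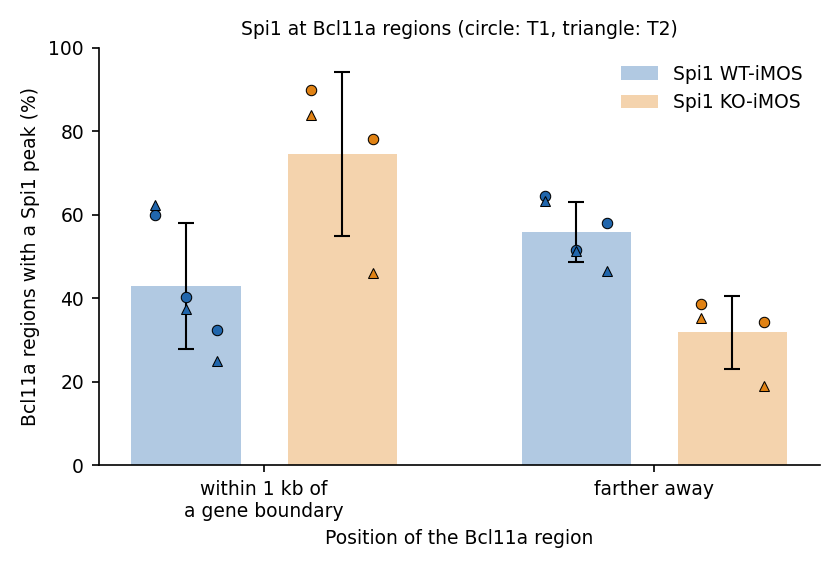
Percentage of Bcl11a regions that hold a Spi1 peak (y axis), for regions within 1 kb of a gene boundary and regions farther away (x axis). Points are libraries, bars means and error bars SD (n = 6 WT-iMOS, n = 4 KO-iMOS). Farther away the 4 KO-iMOS libraries lie between 19.0% and 38.6%, all below the 46.6% to 64.4% of WT-iMOS.

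The loci of the 2 factors themselves were bound. Spi1 was called at its own gene in 6 of 6 WT-iMOS and 4 of 4 KO-iMOS libraries and Bcl11a in 6 of 6, with a region over the gene boundary at chromosome 2, 91082196 to 91083859 (Bcl11a in 5, Spi1 in 6 and 4). A second region inside the gene, chromosome 2, 91096435 to 91097372, was called for Bcl11a in 1, for Spi1 in 5 WT-iMOS and 4 KO-iMOS libraries. At the Bcl11a gene, Spi1 was called in 2 of 6 WT-iMOS and 4 of 4 KO-iMOS libraries. Bcl11a was called there in 0 of 3 T1 and 3 of 3 T2 libraries, with a region 1176 bp inside the gene at chromosome 11, 24077494 to 24077986 (Bcl11a in 3, Spi1 in 2 WT-iMOS and 1 KO-iMOS).

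The third question is how T1 and T2 differ. The Bcl11a T1 lists held a mean of 5882 peaks and the T2 lists 3597 (exact permutation p = 0.2), although T1 replicate 1 (4300) held fewer than T2 replicate 1 (4786). A Bcl11a peak was found at 24.2% and 29.8% of all genes in T1 replicates 2 and 3 and at 9.25% to 14.0% in the other 4 libraries. Of all genes 2.18% were called for Bcl11a in all 3 T1 and in 0 of 3 T2 libraries, and of the genes of the fixed lists 3.82%; list by list no test of T was run. Among them were Fli1 and Selp of the megakaryocyte list, Cd74, Runx2 and Xcr1 of the dendritic list, and Srgn of the mast cell list. The mean difference in peak number, T2 minus T1, was -0.52 on the log2 scale over the 3 sets of libraries, a ratio of 0.698, which did not pass the exact permutation test within sets (p = 0.0833). The ratios were 0.609 for Bcl11a, 0.934 for Spi1 in WT-iMOS and 0.599 for Spi1 in KO-iMOS. Without Spi1 WT-iMOS T2 replicate 1 the difference was -0.64 (exact permutation p = 0.0183). The T difference in Spi1 peaks was not shown to differ between genotypes (interaction -0.64 on the log2 scale, exact permutation p = 0.517). Genome-wide 441 Bcl11a regions were in all T1 and no T2 libraries and 71 the reverse, and 146 and 114 with lists of equal length, but with 3 against 3 no region can go below an exact p of 0.1. Leading T1 regions were chromosome 18, 46525475 to 46526335 at the boundary of Fem1c and chromosome 1, 125435054 to 125435926 at that of Actr3; leading T2 regions were chromosome 4, 125176591 to 125177857, 49343 bp from Zc3h12a, and chromosome 1, 16592824 to 16593534 inside Ube2w. For Spi1, 0 of 19529 regions passed the adjustment with 5 T1 and 5 T2 libraries (Fisher's exact test). The smallest p this test can give is 0.00794, and 3100 regions would have to reach it before any could pass. It also pools the genotypes, so a lack of T difference cannot be read from it. At an unadjusted p under 0.05, 148 were higher in T1 and 8 in T2, and with lists of equal length 62 and 57. The T1 count was 360, 450 and 383 without Spi1 WT-iMOS T1 replicate 2, T1 replicate 3 and T2 replicate 1, and 262, 310 and 302 without KO-iMOS T1 replicate 1, T1 replicate 2 and T2 replicate 1. The T2 count was 29 and 48 without WT-iMOS T2 replicates 2 and 3, and 75, 55, 33 and 43 without KO-iMOS T1 replicate 1, T1 replicate 2, T2 replicate 1 and T2 replicate 2. A region inside Ptk2b, chromosome 14, 66276969 to 66277476, was called in 5 T2 and 0 T1 libraries. The reverse was found inside Lactb2, chromosome 1, 13647749 to 13648343, and inside Cdyl, chromosome 13, 35783140 to 35784083.

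The share of peaks near gene boundaries was not shown to differ between targets in WT-iMOS cells. It was 25.2% ± 11.8 (n = 6) for Bcl11a and 21.2% ± 2.78 (n = 6) for Spi1 (exact permutation p = 0.396). The Bcl11a libraries were uneven: T1 replicates 2 and 3 stood at 38.5% and 40.7% and the other 4 between 10.6% and 21.0%. Without those 2, chosen after the data were seen, the direction turned (-3.07 percentage points, exact permutation p = 0.305). The strongest regions by the deposited −log10 p lay outside genes and were largely common to both targets, to within 2 bp: chromosome 2, 98666253 to 98667331, ranked first for both, and chromosome 9, 35305220 to 35305598, chromosome 14, 124801555 to 124802243, and chromosome 12, 3109872 to 3110144 were among the first 5 of each. The libraries include no control and artefact regions were not filtered out. Signal independent of the antibody therefore cannot be told from binding at these regions, in the overlap of the targets or among regions called in WT-iMOS alone.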

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

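Tests chosen after the results were seen were the other splits of the Bcl11a libraries, the comparison of 2 Bcl11a libraries with Spi1 libraries alone and, for the regions called in WT-iMOS alone, the tests of list length, of weak regions and of a library difference. The division by distance behind the test near gene boundaries was also chosen after the data were seen.

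Libraries far from the others of their set were looked for in 27 combinations of measure and set, and chance marks about 1 in 20. A pair of libraries stood apart. The narrowest peak of Bcl11a WT-iMOS T2 replicate 1 was 196 bp, against 216 to 225 bp in the other Bcl11a libraries. Spi1 KO-iMOS T2 replicate 2 had 31 peaks on unplaced contigs, against 59 to 64 in the other KO-iMOS libraries. Peaks on unplaced contigs, 1755 over all libraries, entered no comparison of regions. Their mean was 122 per library in Bcl11a WT-iMOS, 134 in Spi1 WT-iMOS and 54.2 in Spi1 KO-iMOS (exact permutation p = 0.00952 for the 2 Spi1 sets).

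The genotype split of the 10 Spi1 libraries gave more regions at an unadjusted p under 0.05 than any other split drawn, 3766 against at most 2427, so that 1 of 100 splits reached the real value. With lists of equal length the values were 1291 and at most 765, again 1 of 100. For genes they were 2022 and at most 1676, also 1 of 100. For these 3 counts the values argue against chance assignment of libraries but do not exclude it, since 100 of the 210 possible splits were used. A difference that coincides with genotype stays open. For T1 against T2 in Spi1, 28 of 100 splits gave at least the 156 regions of the real split, so chance cannot be excluded by this count. These splits mix the genotypes, so they say little about T within a genotype. The highest other split gave 2732 and set 5 of the 6 WT-iMOS libraries against all KO-iMOS libraries and 1 WT-iMOS library, which points to the structure of the samples by genotype. For Bcl11a the T split separated 512 regions completely and the highest other split 181; 1 of 10 splits reached the real value, and with 10 splits the share cannot fall under 0.05.

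The first pattern is the 338 regions called in all 6 Spi1 WT-iMOS libraries and in no KO-iMOS library, of which 97.3% hold a Bcl11a region, against 50.3% of the 1495 regions called in all 10. Lists of equal length gave 279 such regions and the highest of the other splits 63. These numbers do not decide on unequal list lengths. Shortening takes more peaks from the longer KO-iMOS lists, which can itself add such regions, and the other splits mix the genotypes. With all peaks the KO-iMOS lists were the longer on average (13637 against 8159 peaks), a difference that works against regions missing from KO-iMOS. A loss of Spi1 at Bcl11a regions wherever they lie was not decided. With equal lengths those near gene boundaries held Spi1 more often in KO-iMOS, by 9.51 percentage points (32.0% against 22.4%, exact permutation p = 0.00952). A fixed length lets losses elsewhere raise this share, and a larger share of all KO-iMOS peaks lay near boundaries. With all peaks, a smaller share of the Spi1 peaks near boundaries lay in Bcl11a regions in KO-iMOS (35.1% against 49.95%, exact permutation p = 0.0190). Additional KO-iMOS peaks outside Bcl11a regions can lower that share. Weak regions that the KO-iMOS lists miss stay open: the median of the lowest percentile in the WT-iMOS lists was 33.6 for the 338 regions and 63.7 for the 1495, on the side this explanation needs, although the 10 leading regions, which the fixed order picks by this percentile, stood at 97.8 to 99.4. A library or processing difference cannot be told apart from genotype, because the narrowest peak of every KO-iMOS list exceeds that of every Spi1 WT-iMOS list by at least 30 bp, and a loss of Spi1 at Bcl11a regions far from genes also stays open.

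The second pattern is the high share of gene-boundary peaks in Bcl11a T1 replicates 2 and 3. Longer lists that reach weaker peaks were argued against: with lists of 2719 peaks the lower of the pair exceeded the highest of the other 4 by 17.5 percentage points. Whole Spi1 libraries under a Bcl11a label were argued against as well: with all peaks their mean Jaccard indices with Spi1 WT-iMOS, 0.225 and 0.227, gave a difference of at most -0.0991 from the lowest among the Spi1 WT-iMOS libraries, 0.326. With equal lengths both were closer to the other Bcl11a libraries than to Spi1 by at least 0.0907, but this counts each of the pair for the other; against the other 4 the margin was at least 0.0530, and with all peaks at least -0.0155, so a part of Spi1 material in them stays open. T1 replicate 1 stood at 20.7%, within the range of the T2 libraries, and no biological explanation was tested.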

How the results depend on the processing

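Divisions by distance to genes and the removal of Bcl11a T1 replicates 2 and 3 together were chosen after the data were seen. Where a result changes, the cause was not tested. Of the alternatives to the main results, 268 kept direction and side of the threshold or, for counts, an equal or close value. Of the rest 2 reversed, 3 were weaker, 10 stronger and 27 counts moved. The kept results include counts of 0 adjusted regions, an outcome that for Bcl11a T1 against T2 was fixed by the number of libraries. They are thus no measure of robustness. For the single gene lists followed through the settings, 174 were kept, 27 were weaker and 3 reversed. Motif results were not run, for want of genome sequence.

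The share of Bcl11a regions with a Spi1 region was 38.7% with equal lengths, against 68.6%. For Spi1 in KO-iMOS against WT-iMOS, covered length gave a difference of 3.56 Mb and peaks within 1 kb of a gene boundary 2712. Equal lengths gave 705 regions higher in KO-iMOS. Regions within 1 kb of a boundary gave 1180 higher in KO-iMOS and 24 in WT-iMOS, and regions farther away 1824 and 738. The share of Bcl11a regions with Spi1 differed by -10.8 points with equal lengths (exact permutation p = 0.00952), -16.2 with regions in at least 3 libraries, 31.6 near boundaries (reversed), -24.0 farther away and -25.0 without Bcl11a T1 replicates 2 and 3. The share of Spi1 peaks in Bcl11a regions differed by -22.9 in T1 alone and -18.8 in T2 alone, which cannot go below an exact p of 0.2. For T1 against T2 in Spi1, equal lengths gave 57 regions higher in T2 and 62 in T1. List calls in WT-iMOS numbered 5 with equal lengths, 0 within 1 kb of a boundary (8 in the main permutation test) and 4 without Bcl11a T1 replicates 2 and 3. Within 1 kb, the Spi1 cell cycle excess (-0.375 genes) and the genotype differences for stem (-8.08 points) and megakaryocyte genes (-2.46) reversed, as did the boundary share of Bcl11a against Spi1 without those replicates (-3.07). The genotype differences for dendritic (-4.75 points) and interferon and inflammation genes (0.419) also changed sign within 1 kb.

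Leaving out single libraries gave KO-iMOS minus WT-iMOS peak differences of 3277 to 7900, T2 minus T1 of -0.72 to -0.31 (log2), 1231 to 4229 regions higher in KO-iMOS, differences of -16.6 to -0.643 points in Bcl11a regions with Spi1, 8 to 75 Spi1 regions higher in T2, 159 to 450 higher in T1, and 5 to 9 list calls.

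Replicate numbers were not taken as pairs, since not every correlation of libraries of the same number was over 0.1. They were 0.0346 to 0.274 for T1 with T2 (all 3 sets), 0.0446 to 0.290 for KO-iMOS with WT-iMOS and -0.130 to 0.0339 for Bcl11a with Spi1. For libraries of different number they were -0.238 to 0.120, -0.290 to 0.171 and -0.0872 to 0.126 in the same order. A pairing by number is therefore not excluded for T1 with T2 or for KO-iMOS with WT-iMOS, and the main tests ignore it. With the replicate block, the share of Spi1 peaks in Bcl11a regions differed by -17.5 points (exact permutation p = 0.0556, the smallest the 36 arrangements allow), the share of Bcl11a regions with Spi1 by -10.0 (p = 0.167), peaks by 4364 (p = 0.167) and T2 minus T1 by -0.52 (p = 0.0547). The block's exact test per region gave 0 regions higher in KO-iMOS and 0 in WT-iMOS at an unadjusted p under 0.05, since it cannot go below 0.0556.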

Other observations

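The tests in this part were chosen after the results were seen. In lists of equal length, T1 and T2 were separated at more regions than any other division of the same libraries in each of the 3 sets, but with all peaks in the Bcl11a set alone. With equal lengths the number of regions in all libraries of a side and none of the other was 260 for Bcl11a (highest other split 136), 317 for Spi1 in WT-iMOS (205) and 1130 for Spi1 in KO-iMOS (454). With all peaks it was 512 for Bcl11a (181), 249 for Spi1 in WT-iMOS (529) and 2330 for Spi1 in KO-iMOS (2354, replicate 1 against 2). With equal lengths the smallest ratio of the T split to the highest other split was 1.55, and 1 of 300 combinations of splits over the 3 sets gave as large a sum of log2 numbers. Both values follow from the T split having been seen as highest in each set, so they do not exclude chance labels. Unequal list length itself is removed by construction with equal lengths, so the ratio is no test of it. The labels give neither the meaning of T nor a library batch.

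The KO-iMOS peak names begin with PWT in T1 and PKO in T2, so the regions missing from KO-iMOS were counted by T. Of the 2409 regions called in all 6 Spi1 WT-iMOS libraries, 55 were in both KO-iMOS T1 lists and neither T2 list, 4 were in both T2 lists and neither T1 list, and 338 were in none of the 4. The KO-iMOS T1 lists are longer on average (16647 peaks against 10627), and over all KO-iMOS regions the same split gave 2147 and 183 with all peaks and 639 and 491 with equal lengths.

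Each library had 4 to 7 peaks on the mitochondrial genome.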
